A study of Homo sapiens with 12 samples.

How the data were processed

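RNA was measured in 12 libraries of Ovcar8 cells, an established line of high-grade serous ovarian cancer. The libraries formed 4 groups of 3: control, CCNE1 overexpression, and CCNE1 overexpression with either of 2 short hairpin RNAs against TMLHE, called shTMLHE 1 and shTMLHE 2 here. Per the labels' protocols, cells carried lentiviral constructs under puromycin selection, RNA was taken with Trizol and a column step with DNase, and libraries were made with the NEBNext Ultra 2 RNA kit. Each sample was placed in its group by its label. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

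The deposited table of counts held whole numbers per gene for 58735 genes, which the authors made from the aligned reads without normalizing them. Per the submitters' processing notes, STAR 2.6.1 and DESeq2 were used with the GRCh38 build. The program that assigned reads to genes, its strand setting and its treatment of reads that match several genes are not given in the sources used here. The gene lengths of the deposited table equalled the exon lengths of GENCODE 29 for 100% of the genes, and coordinates, GC content and transcript lengths were taken from that annotation and from GRCh38. The FPKM deposited by the authors were the same counts divided by gene length and by a library size that was 0.819 to 1.21 times the column total, so a scaling between libraries was already in them. FPKM were used in an alternative only. All per-sample columns were used.

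Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which kept 15378 genes and left out 43357. TMM factors, dispersions and a robust quasi-likelihood fit with 1 mean per group were estimated over all 12 libraries, which left 8 residual degrees of freedom. The comparisons were CCNE1 overexpression minus control, each hairpin group minus CCNE1 overexpression, and shTMLHE 1 minus shTMLHE 2. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene counted as changed at an adjusted p under 0.05. CPM were computed with edgeR's cpm from the TMM-scaled library sizes and are given as mean ± SD, and log2 fold changes carry their standard error (SE). Genes counted for the knockdown passed with both hairpins in the same direction. Genes counted as opposed passed in all 3 comparisons, with the sign of the CCNE1 comparison opposite to that of both hairpins.

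The groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The rule took CCNE1 and TMLHE and, for CCNE1 overexpression, the 12 largest rises and 12 largest falls among changed genes with a mean log2 CPM of at least 1, a gene symbol that is not a clone identifier, and no overlap between the 3 libraries of each group. For the knockdown it took 12 of each direction by the smaller of both hairpins' changes, for the difference between the hairpins 5 of each direction, and for opposed genes 6. It also took up to 4 members of each list by smallest p, a core of homologous recombination genes and the carnitine genes. A gene named outside this rule is marked as such.

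The 28 lists covered G1/S cell cycle and DNA replication, G2/M cell cycle and mitosis, homologous recombination, the Fanconi anaemia pathway, non-homologous end joining, carnitine synthesis and shuttle, fatty acid beta-oxidation, the TCA cycle with alpha-ketoglutarate metabolism, acetyl-CoA supply, alpha-ketoglutarate-dependent demethylases and hydroxylases, histone acetyltransferases, histone deacetylases and replication-dependent histones. They also covered p53 targets, type I interferon response, NF-kappaB targets, the ATF4 response, the unfolded protein response, cholesterol biosynthesis, glycolysis with hypoxia, epithelial-mesenchymal transition, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, immediate early genes, and leukocyte, endothelial and fibroblast markers. The 26 lists with at least 5 tested members were tested with limma's camera against the other genes at a preset correlation of 0.01, leaving CCNE1 and TMLHE out and adjusting over the lists of a comparison. Camera with an estimated correlation was run beside it, as was fry, which tests a list against no change and not against the other genes. Member counts are given after adjustment over all genes and, where they differ, adjusted over the list alone. Unlike the tests, these counts include TMLHE, a member of the carnitine list.

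The alternatives fixed beforehand were DESeq2 size factors (RLE) and upper quartile scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, the replicate number as a block, each library left out in turn, stricter thresholds, and limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1). After the data were seen, 2 alternatives were added. The first took each library's smooth dependence on GC content and transcript length out as an offset, and the second scaled by total counts without TMM. The second moved the median log2 fold change of all tested genes from 0.034 to 0.43 for shTMLHE 1 and from 0.031 to 0.56 for shTMLHE 2, so directions in the hairpin comparisons are relative to the TMM scale. Hairpin comparisons shared the CCNE1 libraries, and 20 simulations of unchanged groups gave the correlations and covariances that this sharing produces when no gene changes. Almost no genes were called in these simulations, so they cannot show what overlap the sharing adds among real calls.

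Depth was 14.1 to 21.5 M counts per library. The common biological coefficient of variation was 0.0651. No pair of replicates agreed within sampling noise, the chi-square per degree of freedom over genes with at least 20 counts in the pair being 2.09 to 5.63, so each library counted as 1 replicate. The steps were tested on simulated counts for the same 15378 genes. Of the 67 genes changed 2-fold in each comparison, 67.2% were called in the right direction for CCNE1 overexpression, 62.7% for shTMLHE 1, 58.2% for shTMLHE 2 and 71.6% for the difference between the hairpins, with 2.84%, 6.62%, 5.00% and 5.88% of calls on unchanged genes. These fits gave 140 to 153 calls each, far fewer than the real data, so the rates in the real data may differ. Exons shared with overlapping genes were measured from the annotation, since without a stated strand setting reads of overlapping genes cannot be told apart. A GC and length trend was also planted, as the model that removes it had fitted it to the real libraries. With it, 9940 of 10128 calls fell on unchanged genes as counted, and 17 of 186 with the trend removed. The model thus removed its own trend, which cannot show that the offset is adequate for the real data.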

Results

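Gene expression was profiled by RNA sequencing in Ovcar8 high-grade serous ovarian cancer cells in 4 groups of 3 libraries. Control cells were set beside cells that overexpressed CCNE1, the gene of cyclin E1, which drives entry into S phase with its partner kinase CDK2. The remaining groups combined CCNE1 overexpression with either of 2 hairpins against TMLHE, which encodes the alpha-ketoglutarate-dependent enzyme at the start of carnitine synthesis. By its title, the series concerns alpha-ketoglutarate, carnitine, histone acetylation and homologous recombination. Totals were 14.1 to 16.6 M counts in control, 15.8 to 21.5 M with CCNE1, 14.9 to 16.3 M with shTMLHE 1 and 14.6 to 19.9 M with shTMLHE 2.

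The groups differed in the make-up of their libraries. Ribosomal protein genes of the fixed list took 11.7 ± 0.2% of counts in control and 12.8 ± 0.173% with CCNE1, against 6.74 ± 0.145% with shTMLHE 1 and 6.90 ± 0.0586% with shTMLHE 2 (SD, n = 3). Mitochondrially encoded genes took 4.18 ± 0.131%, 3.17 ± 0.0351%, 5.34 ± 0.168% and 2.93 ± 0.0603% in the same order. The mean GC content of the counted genes was 53.8%, 53.5%, 52.3% and 50.5%. The first principal component held 63% of the variance and separated both hairpin groups from control and CCNE1, and the next held 11.4% and separated the hairpin groups from each other.

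The transcripts that define the groups followed their labels. CCNE1 (ENSG00000105173, chromosome 19, 29811898 to 29824308 in GRCh38) stood at 33.1 ± 1.28 CPM in control and 1001 ± 34.0 with CCNE1 (SD, n = 3), a log2 fold change of 4.92 ± 0.04 (SE, edgeR adjusted p = 2.88e-44). It stood at 1269 ± 49.0 CPM with shTMLHE 1 and 847 ± 21.2 with shTMLHE 2, log2 fold changes of 0.34 and -0.24 against the CCNE1 group, of which the latter became 0.29 under total counts and 0.10 with the GC and length trend removed. TMLHE (ENSG00000185973, chromosome X, 155490115 to 155669944) stood at 16.5 ± 1.62 CPM in control and 15.7 ± 2.69 with CCNE1, a difference that did not pass the test (adjusted p = 0.778). It fell to 0.956 ± 0.286 CPM with shTMLHE 1, a log2 fold change of -4.04 ± 0.24 (adjusted p = 5.99e-18), and to 0.482 ± 0.241 with shTMLHE 2, a change of -5.07 ± 0.26 (adjusted p = 2.95e-20). TMLHE had 177 to 293 counts in each control and CCNE1 library and 6 to 21 in each hairpin library.

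**Figure D1:**
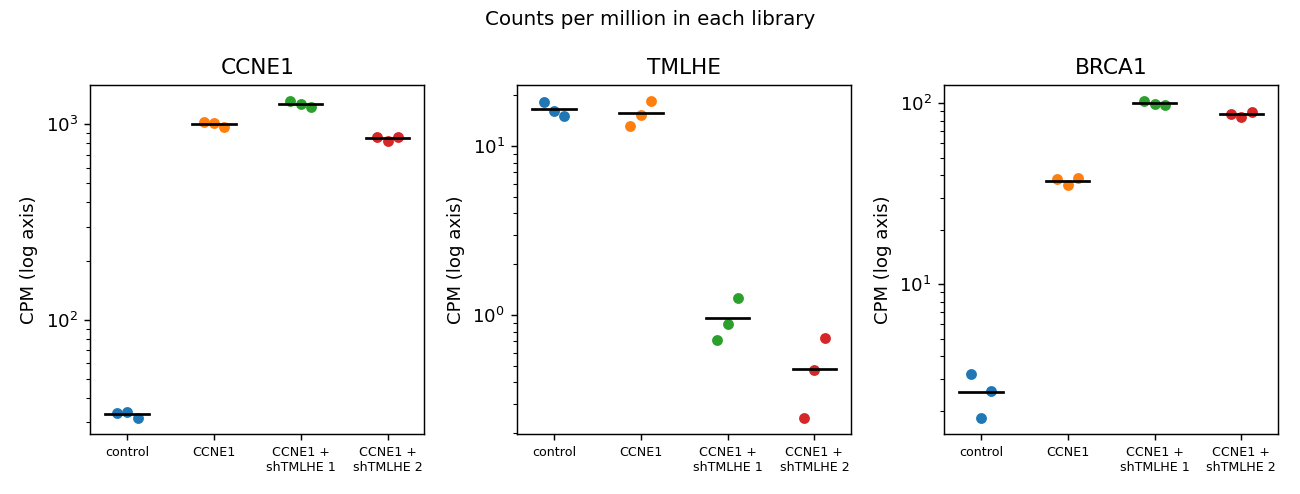
CPM of CCNE1, TMLHE and BRCA1 on log axes, with a point for each of the 3 libraries of a group and a line at the group mean. CCNE1 rises from a mean of 33.1 to 1001 CPM, TMLHE falls from 15.7 to 0.956 and 0.482 CPM with the hairpins, and BRCA1 rises from 2.53 to 37.3 CPM with CCNE1.

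The question of the CCNE1 comparison was which transcripts differed between cells with CCNE1 overexpression and control cells. The labels give a single population of each, so overexpression cannot be told apart from other differences between the populations. BRCA1, a central homologous recombination gene (ENSG00000012048, chromosome 17, 43044295 to 43170245), rose from 2.53 ± 0.692 to 37.3 ± 1.81 CPM (SD, n = 3), a log2 fold change of 3.86 ± 0.12 (SE, edgeR adjusted p = 1.34e-25). The receptor tyrosine kinase ROR1 rose by 3.71 ± 0.72 on the log2 scale, the interferon-induced OAS3 by 3.62 ± 0.51 and the MHC class II invariant chain CD74 by 2.81 ± 0.30. AFAP1L2 rose by 3.12, DMBT1 by 2.93, VWA1 by 2.73, CDH23 by 2.69, OCA2 by 2.69 and podoplanin (PDPN) by 2.6. EMC10, a subunit of the ER membrane protein complex, fell by 8.00 ± 0.29, from 45.1 ± 3.47 to 0.158 ± 0.138 CPM.

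Phospholipase PLCB1 fell by 4.15 on the log2 scale, cardiac actin ACTC1 by 3.53, interferon-induced IFI27 by 3.29, AEBP1 by 3.18, FILIP1L by 3.00 and NACAD by 2.68. Troponin C TNNC1 fell by 2.65, the olfactory receptor pseudogene OR7E19P by 2.64, the transcription factor TCF21 by 2.36 and the growth factor MDK by 2.22. The AFAP1L2 value was 8.01 without control replicate 2. With a library left out ROR1 was at 2.729 to 4.62 and OAS3 at 2.985 to 4.277. CBSL at 3.45 and XAGE1B at -3.84 also met the rule, but both have near-identical copies between which reads can be split, and CBSL was at 1.77 without CCNE1 replicate 3. The edgeR call of CBSL was lost when control replicate 1, 2 or 3 was left out (log2 fold changes of 3.32, 3.55 and 3.49). With only the compared groups fitted neither CBSL (adjusted p = 0.131) nor XAGE1B (0.0535) passed.

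In all, 6802 of 15378 tested genes changed with CCNE1, 3866 higher and 2936 lower, and 941 of them changed at least 2-fold (563 higher, 378 lower). Fold changes followed GC content across genes (Spearman -0.383) and less so transcript length (0.147). These 2 properties together accounted for 9.48% of the variance of fold changes, genes not being independent. With that trend removed 5573 genes passed, 4436 of them also called in the same direction as counted and 44 in the opposite direction.

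Both cell cycle lists rose with CCNE1. Of 50 G1/S and DNA replication genes, 37 rose and 2 fell (39 and 2 adjusted over the list alone), with a median log2 fold change of 0.36 (camera adjusted p = 6.29e-11, and adjusted p = 0.00609 with an estimated correlation). Cyclin D1 (CCND1) rose by 0.81 ± 0.04 on the log2 scale, the ribonucleotide reductase subunit RRM1 by 0.76 ± 0.05 and the helicase subunit MCM5 by 0.68 ± 0.04. Of 41 G2/M and mitosis genes, 33 rose and 1 fell, the same as adjusted over the list alone, with a median of 0.59 (adjusted p = 4.97e-16, and 0.00752 with an estimated correlation). The mitotic kinesin KIF11 rose by 1.36 ± 0.08, anillin (ANLN) by 1.23 ± 0.05 and topoisomerase TOP2A by 1.15 ± 0.04. The medians were 0.37 and 0.40 with the GC and length trend removed, and both lists still passed (adjusted p = 6.27e-16 and 3.38e-14).

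Of 36 tested homologous recombination genes, 16 rose and 5 fell with CCNE1, the same as adjusted over the list alone, with a median of 0.37 (camera adjusted p = 0.00814, and 0.0482 with an estimated correlation). Beside BRCA1, the nucleases DNA2 and MRE11 rose by 1.40 ± 0.15 and 1.25 ± 0.11 on the log2 scale. BRCA2 rose by 0.95 ± 0.25 (edgeR adjusted p = 0.0023) and RBBP8, the end-resection factor CtIP, by 0.44 ± 0.16 (adjusted p = 0.0212). PALB2 was at 0.39 ± 0.21 (adjusted p = 0.145) and RAD51C at 0.12 ± 0.12 (adjusted p = 0.449), and the latter was at -0.11 with the GC and length trend removed. XRCC3 was at -0.28, with 76.7% of its exon bases shared with overlapping genes, so its source is uncertain. With the trend removed the list no longer passed (median 0.13, adjusted p = 0.061), nor did BRCA2 (0.48), RBBP8 (0.10) or XRCC3 (-0.17). RBBP8 also did not pass with only the compared groups fitted (adjusted p = 0.104). Without CCNE1 replicate 2 the calls of BRCA2 (0.61) and RBBP8 (0.25) were also lost, as were those of RBBP8 without control replicate 1 or 3 (0.42 and 0.37) and of XRCC3 without control replicate 1 (-0.21).

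Non-homologous end joining genes rose in 7 of 15 cases and fell in 0, or 8 and 0 adjusted over the list alone, led by PRKDC, the DNA-PK catalytic subunit, at 0.62 ± 0.04 and XRCC5 (Ku80) at 0.41 ± 0.04. That list passed at adjusted p = 0.024 and gave adjusted p = 0.0837 with an estimated correlation. Of 26 ATF4 response genes 13 rose and 3 fell, the same as adjusted over the list alone (median 0.25, adjusted p = 0.000328, and 0.018 with an estimated correlation). The amino acid transporter SLC7A5 rose by 1.14 ± 0.04, and the serine synthesis enzymes PSAT1 and PHGDH by 0.82 ± 0.04 and 0.54 ± 0.03. In the epithelial-mesenchymal list 11 of 28 genes rose and 8 fell, the same as adjusted over the list alone (median 0.07, adjusted p = 0.004, and 0.0837 with an estimated correlation). Its leading members were both epithelial keratins, KRT7 at 2.15 ± 0.03 and KRT18 at 0.97 ± 0.03, and matrix genes, THBS1 at 1.35 ± 0.05 and fibronectin (FN1) at 1.11 ± 0.03.

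Ribosomal protein genes rose in 28 and fell in 3 of 47 cases (30 and 3 adjusted over the list alone), with a median of 0.15 (adjusted p = 4.97e-05, and adjusted p = 0.355 with an estimated correlation). RPL7 rose by 0.82 ± 0.04 and RPS24 by 0.71 ± 0.04. Of 13 mitochondrially encoded mRNAs 11 fell and 1 rose, the same as adjusted over the list alone, with MT-CO1 at -0.76 ± 0.03 and MT-ND5 at -0.40 ± 0.03 (list median -0.22, adjusted p = 1.78e-06, and 0.155 with an estimated correlation).

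NF-kappaB targets fell in 8 and rose in 1 of 20 cases, the same as adjusted over the list alone (median -0.37, adjusted p = 0.0127, and 0.0837 with an estimated correlation), with the adhesion molecule ICAM1 at -0.95 ± 0.07. Of 19 unfolded protein response genes 9 fell and 3 rose, the same as adjusted over the list alone, among them the chaperones HYOU1 at -0.54 ± 0.04 and PDIA4 at -0.39 ± 0.04 (list median -0.13, adjusted p = 0.0465, and 0.107 with an estimated correlation). That call was lost without control replicate 3 (adjusted p = 0.0629) and without CCNE1 replicate 1, 2 or 3 (0.0564, 0.0514 and 0.0642), and with RLE size factors (0.0504). The p53 target CDKN1A, an inhibitor of cyclin-dependent kinases, fell by 1.12 ± 0.07 (edgeR adjusted p = 7.68e-16).

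The other lists did not pass with CCNE1 overexpression in camera. Carnitine genes rose in 0 and fell in 4 of 13 cases, the same as adjusted over the list alone (adjusted p = 0.29). Of these, CPT2 fell by 0.60 ± 0.18, the carrier SLC25A20 by 0.54 ± 0.17 and CRAT by 0.23 ± 0.07. Each of these 3 edgeR calls was lost without a single library, at -0.41 without CCNE1 replicate 2 for CPT2, and at -0.40 and -0.14 without CCNE1 replicate 1 for SLC25A20 and CRAT, and the last 2 were lost with the trend removed (-0.41 and -0.11). SLC22A5 was at -0.46 (adjusted p = 0.14), and passed at -0.75 without CCNE1 replicate 3. ALDH9A1 was at 0.04 and CPT1A at -0.01, neither passing.

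Members higher and lower were 4 and 4 of 16 for the Fanconi anaemia pathway (adjusted p = 0.706), 6 and 8 of 22 for fatty acid beta-oxidation (0.576), 12 and 8 of 29 for the TCA cycle with alpha-ketoglutarate metabolism (0.29), 7 and 4 of 17 for acetyl-CoA supply (0.973) and 15 and 17 of 48 for alpha-ketoglutarate-dependent demethylases and hydroxylases (0.15). They were 4 and 5 of 16 for histone acetyltransferases (0.706), 5 and 7 of 18 for histone deacetylases (0.706), 0 and 3 of 18 for replication-dependent histones (0.706), 3 and 7 of 24 for p53 targets (0.15), 6 and 7 of 27 for the interferon response (0.299) and 6 and 8 of 24 for cholesterol biosynthesis (0.29). They were 10 and 7 of 26 for glycolysis with hypoxia (0.514), 13 and 4 of 39 for nuclear-encoded oxidative phosphorylation (0.273), 3 and 4 of 15 for immediate early genes (0.533), 0 and 1 of 5 for endothelial markers (0.567), 2 and 2 of 4 for fibroblast markers, and 0 and 0 of 2 for leukocyte markers, the last 2 without a test. Adjusted over the list alone these counts changed to 16 and 8 for the TCA list, 13 and 8 for glycolysis, 6 and 9 for beta-oxidation, 7 and 5 for acetyl-CoA supply, 15 and 18 for demethylases and hydroxylases, 5 and 6 for acetyltransferases, 7 and 8 for cholesterol and 0 and 1 for histones. Median, mean and test did not share a sign for glycolysis, acetyl-CoA supply, deacetylases, acetyltransferases, histones, the interferon response, cholesterol and endothelial markers. With the GC and length trend removed the median changed sign for acetyl-CoA supply (-0.09), acetyltransferases (0.05), the interferon response (0.04) and immediate early genes (0.03). Under total counts it did so for deacetylases, histones and cholesterol (each -0.01).

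The hairpin comparisons asked what changed with hairpins against TMLHE in cells with CCNE1 overexpression. No group with another hairpin was labelled, so TMLHE knockdown cannot be told apart here from an effect of any hairpin or of selection. The metallothionein MT1E, from a family that binds zinc and copper, had the largest shared rise among genes taken by the rule. It rose from 9.93 ± 2.24 CPM with CCNE1 to 389 ± 13.2 with shTMLHE 1 and 298 ± 8.36 with shTMLHE 2 (SD, n = 3), log2 fold changes of 5.29 ± 0.10 and 4.90 ± 0.10 (SE, edgeR adjusted p = 3.30e-18 and 4.34e-18). MT1M rose by 5.07 and 4.09 and MT1X by 4.29 and 3.22, and the zinc exporter SLC30A1 rose by 2.86 and 3.82. Metallothionein genes resemble each other in sequence, so reads can be split between members. The axon guidance factor SLIT2 rose by 2.71 and 3.94, TP53INP1, a p53 target, by 3.09 and 2.58, and titin (TTN) by 2.57 and 2.6. ZNF695, CCDC144A, ZNF267 and ANKRD26 rose by 2.53 to 3.56 with both hairpins. FTX was at 3.79 and 4.38, and it shared 44.3% of its exon bases with overlapping genes.

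Beside TMLHE, the largest shared falls among genes taken by the rule were in DMBT1 (-2.65 and -2.88 for shTMLHE 1 and 2), the FGF receptor family member FGFRL1 (-3.31 and -2.62), the ciliary gene FUZ (-2.74 and -2.59), NKPD1 (-3.33 and -2.56), the selenoprotein SELENOM (-2.50 and -2.86) and the RNase P/MRP subunit relative RPP25L (-3.38 and -2.46). The bile acid-binding protein FABP6 fell by 2.45 and 3.74, the phosphatase PTP4A3 by 2.42 and 2.75 and LRRC4B by 2.31 and 2.6. EEF1AKMT4 was at -3.29 and -2.42 with 46.8% of its exon bases shared, and U2AF1L5 at -2.40 and -2.45 has a near-identical copy, so both are uncertain. With only the compared groups fitted U2AF1L5 no longer passed with shTMLHE 1 (adjusted p = 0.0599). The shTMLHE 2 value of TP53INP1 was 3.98 without CCNE1 replicate 1.

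With shTMLHE 1, 9338 of 15378 genes changed in edgeR's test (4673 higher, 4665 lower), 2969 of them at least 2-fold. With shTMLHE 2, 11224 changed (5653 higher, 5571 lower), 5852 of them at least 2-fold. Under total counts the shares of calls that were higher were 75.9% and 70.7%, against 50% and 50.4% with TMM. Fold changes followed GC content and transcript length across genes, with Spearman values of -0.378 and 0.378 for shTMLHE 1 and -0.647 and 0.378 for shTMLHE 2, and both properties together took 18.6% and 41.0% of the variance. In the 10% of genes with the lowest GC content (median 37.3%) the median log2 fold change with shTMLHE 2 was 1.28, and in the 10% with the highest (64.5%) it was -1.30. With that trend removed 8532 and 9544 genes passed. Of those, 6725 and 6880 were called in the same direction as counted and 340 and 1192 in the opposite direction.

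**Figure D2:**
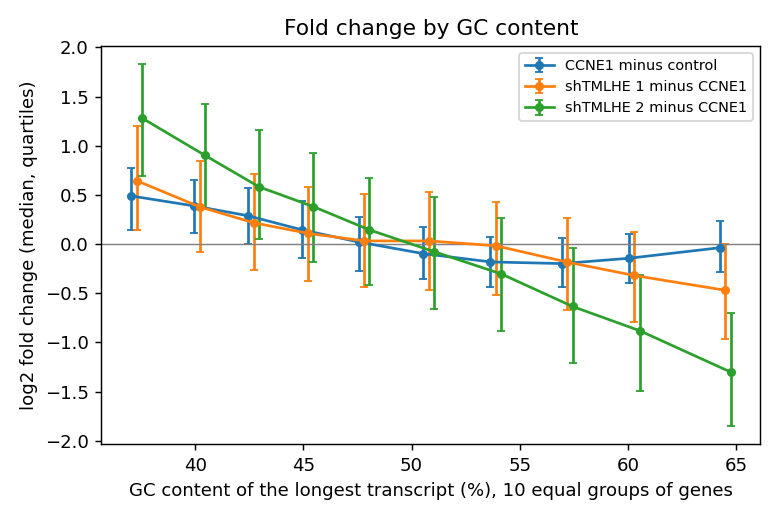
Median log2 fold change (points) with quartiles (bars) in 10 equal groups of the tested genes ordered by GC content of the longest transcript, in percent, for the CCNE1 comparison and both hairpin comparisons. With shTMLHE 2 the median goes from 1.28 in the lowest group to -1.30 in the highest, with shTMLHE 1 from 0.64 to -0.47, and with CCNE1 from 0.49 to -0.04 by way of -0.20 in the group with a median GC content of 57.2%.

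Both hairpins changed 7206 genes in the same direction (3570 higher, 3636 lower) and 894 in opposite directions. Independent lists of these sizes would share 1718 higher and 1690 lower genes. Simulated unchanged groups shared 0.05 genes on average. Only 0.6 and 0.45 genes were called there per hairpin, so that value cannot show what the shared CCNE1 libraries add to the overlap. Under total counts 77.7% of the shared calls were higher, against 49.5% with TMM. Once the GC and length trend was removed 6046 genes were shared (2417 higher, 3629 lower), of which 4267 were also shared in the same direction as counted. Across genes, which are not independent replicates, the log2 fold changes of both hairpins correlated at 0.769 against 0.533 in the simulation, with a covariance of 0.875 against 0.0553. The simulated correlation comes from groups without changes, whose fold changes hold noise alone, so only the covariances can be set side by side. The difference of covariances, 0.819, estimates the shared part. The covariance was 0.583 with the GC and length trend removed, and 0.665 as counted and 0.344 with the trend removed over the 12259 genes with a mean log2 CPM of at least 1, so the size of that part depended on the genes and the fit. With 3 CCNE1 libraries these could not be split into parts of at least 2, so part of the excess overlap may come from the shared libraries.

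Ribosomal protein genes fell with both hairpins. Of 47 members, 46 fell and 0 rose with shTMLHE 1 and 43 fell and 3 rose with shTMLHE 2, the same as adjusted over the list alone. The median log2 fold changes were -1.29 and -1.45 (camera adjusted p = 6.91e-78 and 3.61e-36, and 0.00219 and 0.0239 with an estimated correlation). RPLP0 fell from 11730 ± 113 CPM with CCNE1 to 4299 ± 90.5 and 3765 ± 23.8 (SD, n = 3), log2 fold changes of -1.45 ± 0.02 and -1.64 ± 0.02. Nuclear-encoded oxidative phosphorylation genes fell in 38 and rose in 0 of 39 cases with shTMLHE 1, and fell in 32 and rose in 3 with shTMLHE 2, the same as adjusted over the list alone. Their medians were -0.91 and -1.18 (adjusted p = 1.03e-26 and 1.68e-18, and 0.000736 and 0.00154 with an estimated correlation). Cytochrome c1 (CYC1) fell by 1.29 and 2.06, UQCRC1 of complex III by 1.20 and 1.76 and NDUFS8 of complex I by 1.64 and 2.12. Removing the GC and length trend gave medians of -1.02 and -0.96 for ribosomal proteins and -0.69 and -0.92 for oxidative phosphorylation, and under total counts -0.90, -0.92, -0.52 and -0.66.

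The TCA cycle and alpha-ketoglutarate list fell in 20 and rose in 4 of 29 cases with shTMLHE 1 (20 and 5 adjusted over the list alone) and fell in 20 and rose in 5 with shTMLHE 2 (21 and 5). Its medians were -0.39 and -0.52 on the TMM scale (camera adjusted p = 0.000394 and 0.00167, and 0.0778 and 0.147 with an estimated correlation), and 0.01 and 0.01 under total counts. With the GC and length trend removed the list passed with both hairpins (camera adjusted p = 6.49e-05 and 2.46e-07, and 0.0295 and 0.0207 with an estimated correlation). Malate dehydrogenase MDH2 fell by 1.05 ± 0.04 and 1.47 ± 0.04 and PHGDH by 0.74 ± 0.03 and 1.79 ± 0.03. Citrate synthase CS and IDH1 fell by 1.46 ± 0.04 and 2.40 ± 0.11 with shTMLHE 1, and IDH2 by 2.29 ± 0.04 with shTMLHE 2. Glycolysis and hypoxia genes fell in 15 and rose in 6 of 26 cases with shTMLHE 1 and fell in 17 and rose in 7 with shTMLHE 2, the same as adjusted over the list alone. Their medians were -0.31 and -0.39 on the TMM scale (camera adjusted p = 0.000624 and 0.00167, and 0.0412 and 0.0819 with an estimated correlation), and 0.08 and 0.14 under total counts. With the GC and length trend removed the call with shTMLHE 2 was lost (adjusted p = 0.123). GAPDH fell by 1.43 ± 0.02 and 1.55 ± 0.02 and TPI1 by 0.97 ± 0.03 and 1.44 ± 0.03. Under total counts the TCA and glycolysis lists were no longer called with either hairpin (adjusted p = 0.0939 to 0.117).

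G1/S and DNA replication genes fell in 34 and rose in 6 of 50 cases with shTMLHE 1, the same as adjusted over the list alone, with a median of -0.53 (adjusted p = 1.15e-05, and 0.0187 with an estimated correlation), or -0.13 under total counts, where the list still passed. With shTMLHE 2, 26 fell and 14 rose (27 and 14 adjusted over the list alone), with a median of -0.29 that became 0.24 under total counts (adjusted p = 0.0218, 0.165 with an estimated correlation and 0.321 under total counts). With the GC and length trend removed the list passed with both hairpins (camera adjusted p = 1.06e-07 and 0.000187, and 0.0134 and 0.0489 with an estimated correlation). The licensing factor CDT1 fell by 1.82 ± 0.04 and 2.50 ± 0.04 and MCM5 by 0.95 ± 0.04 and 2.08 ± 0.04. G2/M and mitosis genes rose in 23 and fell in 12 of 41 cases with each hairpin, the same as adjusted over the list alone. Their medians were 0.35 and 0.44 on the TMM scale (camera adjusted p = 0.00181 and 0.0324, and 0.129 and 0.205 with an estimated correlation), and 0.75 and 0.97 under total counts. CDK1 rose by 1.93 ± 0.08 and 2.15 ± 0.08 and the kinesin CENPE by 3.43 ± 0.12 with shTMLHE 2, while the mitotic kinase PLK1 fell by 1.00 ± 0.04 with shTMLHE 1. With the GC and length trend removed the medians were 0.14 and 0.00298, and the list passed with shTMLHE 1 alone (adjusted p = 0.0198 against 0.689). The call with shTMLHE 1 was lost there with an estimated correlation (adjusted p = 0.141). The difference between the hairpins was not called for this list as counted (adjusted p = 0.884) and was called with the trend removed (0.0473).

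Homologous recombination genes did not pass as a list with either hairpin. Of 36 members, 13 rose and 5 fell with shTMLHE 1, the same as adjusted over the list alone (median 0.13, camera adjusted p = 0.191), and 19 rose and 11 fell with shTMLHE 2 (20 and 11 adjusted over the list alone, median 0.59, or -0.00091 with the GC and length trend removed, adjusted p = 0.137). BRCA1 rose further, to 100 ± 2.83 and 86.7 ± 3.12 CPM (SD, n = 3), log2 fold changes of 1.43 ± 0.07 and 1.22 ± 0.07 that were 0.92 and 0.30 with the GC and length trend removed. BRCA2 rose by 2.03 ± 0.19 and 2.41 ± 0.18, RBBP8 by 0.72 ± 0.14 and 1.38 ± 0.14 and PALB2 by 0.76 ± 0.19 and 0.71 ± 0.19. With that trend removed BRCA2 was at 1.00 and 0.80, RBBP8 at 0.35 and 0.51, and PALB2 at 0.48 and, no longer passing, 0.05. RAD51C was at -0.02 with shTMLHE 1 (adjusted p = 0.881) and 0.44 with shTMLHE 2 (adjusted p = 0.000597), values that became 0.37 for shTMLHE 1 under total counts, where it passed, and -0.09 for shTMLHE 2 with the trend removed. XRCC3, whose exons are mostly shared, was at -0.79 and -1.69.

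Carnitine genes did not pass as a list, with 4 higher and 7 lower of 13 for shTMLHE 1 (adjusted p = 0.753) and 2 higher and 6 lower for shTMLHE 2 (adjusted p = 0.137), the same as adjusted over the list alone. TMLHE, the target of the hairpins, is among the 13 and among the lower members with both hairpins, but was left out of the test. Carnitine acetyltransferase CRAT fell by 0.89 ± 0.07 and 2.26 ± 0.08 and the carnitine transporter SLC22A5 by 1.10 ± 0.27 and 1.68 ± 0.28, while ALDH9A1 rose by 0.59 ± 0.05 and 0.43 ± 0.05. CPT1A rose by 1.03 ± 0.23 with shTMLHE 1 and was at 0.32 ± 0.23 with shTMLHE 2 (adjusted p = 0.219), where it passed at 0.85 under total counts, and SLC25A20 fell by 1.92 ± 0.20 with shTMLHE 1 and was at -0.32 ± 0.18 with shTMLHE 2 (adjusted p = 0.101), a value of 0.21 under total counts. CPT2 passed with neither hairpin as counted (-0.37 and -0.19, or 0.03 and 0.34 under total counts), and passed with shTMLHE 1 at -0.43 with the GC and length trend removed. CPT1A and SLC25A20 passed with shTMLHE 2 when CCNE1 replicate 1 was left out (0.62 and -0.46), and CPT2 passed with shTMLHE 1 without CCNE1 replicate 2 or shTMLHE 1 replicate 1 (-0.56 and -0.52).

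Histone acetyltransferase genes rose in 9 and fell in 2 of 16 cases with shTMLHE 1, the same as adjusted over the list alone (median 0.62, adjusted p = 0.0325, 0.162 with an estimated correlation and 0.0972 with the GC and length trend removed). With shTMLHE 2, 11 rose and 5 fell, the same as adjusted over the list alone, without passing as a list (median 0.78, adjusted p = 0.137). The coactivator NCOA3 rose by 1.40 ± 0.07 and 1.56 ± 0.07, HAT1 by 1.40 ± 0.11 and 2.12 ± 0.11, and KAT8 fell by 0.91 ± 0.06 and 1.32 ± 0.06. Histone deacetylase genes were 1 higher and 10 lower of 18 with shTMLHE 1 and 3 higher and 12 lower with shTMLHE 2, the same as adjusted over the list alone, and did not pass (medians -0.28 and -0.57, or 0.11 and -0.04 under total counts, adjusted p = 0.191 and 0.0801). Alpha-ketoglutarate-dependent demethylases and hydroxylases rose in 25 and fell in 8 of 48 cases with shTMLHE 1 (26 and 8 adjusted over the list alone), with a median of 0.30. They passed narrowly there (adjusted p just under 0.05, 0.0813 with an estimated correlation and 0.173 with the trend removed) and not with shTMLHE 2 (26 higher, 12 lower, median 0.35, adjusted p = 0.102).

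Epithelial-mesenchymal genes rose in 16 and fell in 6 of 28 cases with shTMLHE 1, the same as adjusted over the list alone (median 0.48, adjusted p = 2.30e-05, and 0.0257 with an estimated correlation). The matrix genes TGFBI, SPARC and COL1A1 rose by 1.89 ± 0.07, 1.72 ± 0.03 and 1.36 ± 0.03, and KRT18 fell by 0.74 ± 0.03. With shTMLHE 2, 17 rose and 9 fell, the same as adjusted over the list alone (median 0.57, adjusted p = 0.0749), and the list passed without shTMLHE 2 replicate 1 (0.0456). Mitochondrially encoded mRNAs rose in 10 and fell in 3 of 13 cases with shTMLHE 1, the same as adjusted over the list alone, with MT-ND5 at 1.19 ± 0.03 and MT-ND4 at 0.85 ± 0.03 (list median 0.77, adjusted p = 4.74e-07, and 0.129 with an estimated correlation). With shTMLHE 2 this list was 3 higher and 8 lower, with MT-CO2 at -1.54 ± 0.03 and MT-CO3 at -1.43 ± 0.03, and did not pass (median -0.13, or 0.40 under total counts, adjusted p = 0.0874).

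**Figure D3:**
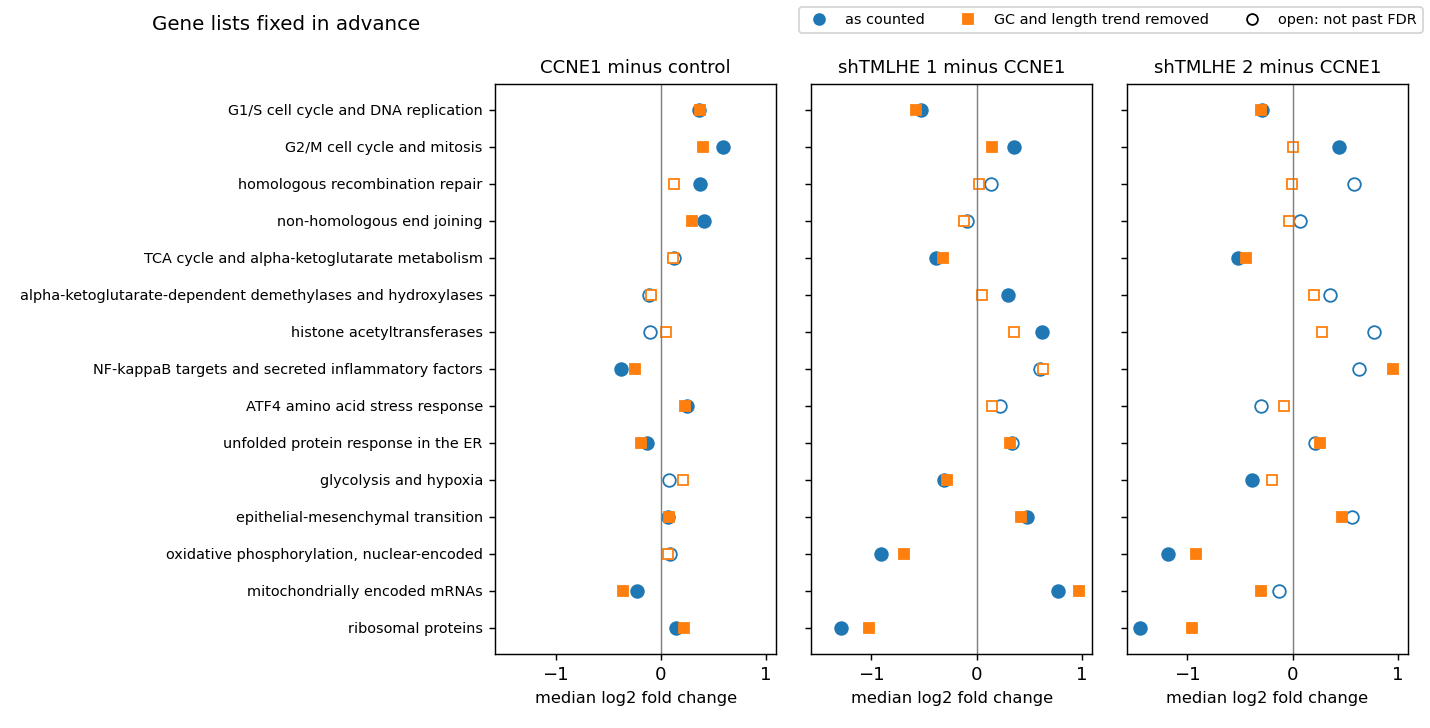
Median log2 fold change of the members of each gene list that passed in at least 1 comparison, for the 3 comparisons. Circles show values as counted, squares show values with the GC and length trend removed, and filled symbols passed camera at an adjusted p under 0.05. Ribosomal proteins lie at -1.29 and -1.45 with the hairpins as counted, and at -1.02 and -0.96 with the trend removed. The TCA and glycolysis medians with the hairpins, below 0 here, lie above 0 under total counts.

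The lists left did not pass with either hairpin. Members higher and lower with shTMLHE 1 were 3 and 6 of 16 for the Fanconi anaemia pathway (adjusted p = 0.445), 5 and 6 of 15 for non-homologous end joining (0.266), 2 and 12 of 22 for fatty acid beta-oxidation (0.0524), 3 and 9 of 17 for acetyl-CoA supply (0.296), 3 and 4 of 18 for replication-dependent histones (0.841), 12 and 5 of 24 for p53 targets (0.191) and 6 and 8 of 27 for the interferon response (0.396). They were 8 and 4 of 20 for NF-kappaB targets (0.604), 13 and 6 of 26 for the ATF4 response (0.323), 11 and 5 of 19 for the unfolded protein response (0.191), 9 and 9 of 24 for cholesterol biosynthesis (0.323), 5 and 3 of 15 for immediate early genes (0.445) and 2 and 0 of 5 for endothelial markers (0.606). With shTMLHE 2 the same lists had 7 and 8 (0.442), 7 and 6 (0.339), 4 and 14 (0.109), 5 and 5 (0.651), 2 and 6 (0.983), 12 and 7 (0.634), 7 and 10 (0.634), 12 and 2 (0.137), 9 and 13 (0.329), 11 and 5 (0.109), 12 and 10 (0.0663), 4 and 5 (0.746) and 1 and 1 (0.886). Fibroblast markers were 3 higher and 0 lower of 4, then 2 and 1, and leukocyte markers 0 and 0 of 2, then 0 and 1, without a test. The cholesterol enzyme HMGCS1 rose by 2.62 ± 0.06 with shTMLHE 2.

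Adjusted over the list alone, the counts of these lists changed with shTMLHE 1 to 6 and 6 for end joining, 13 and 5 for p53 targets, 12 and 5 for the unfolded protein response and 3 and 1 for fibroblast markers. With shTMLHE 2 they changed to 8 and 7 for end joining, 2 and 5 for histones and 3 and 5 for immediate early genes, and to 26 and 13 for the demethylases and hydroxylases. Beta-oxidation passed with shTMLHE 1 without CCNE1 replicate 1, 2 or 3 (0.0473, 0.0468 and 0.0475) or without shTMLHE 1 replicate 1 or 2 (0.0436 and 0.0499), and cholesterol biosynthesis passed with shTMLHE 2 without shTMLHE 2 replicate 1 (0.0456). With the GC and length trend removed cholesterol biosynthesis (1.79e-06), the epithelial-mesenchymal list (1.23e-06), NF-kappaB targets (0.000733), the unfolded protein response (0.00774), beta-oxidation (0.0145), immediate early genes (0.0145) and mitochondrially encoded mRNAs (0.000733) passed with shTMLHE 2, and p53 targets and the unfolded protein response (0.0458 for each) with shTMLHE 1. An estimated correlation in that fit took away the calls of immediate early genes (adjusted p = 0.189) and mitochondrially encoded mRNAs (0.208) with shTMLHE 2, and of p53 targets (0.198) and the unfolded protein response (0.135) with shTMLHE 1. Median, mean and test did not share a sign with either hairpin for the Fanconi pathway, end joining and histones, nor with shTMLHE 2 for acetyl-CoA supply, the interferon response, immediate early genes and endothelial markers.

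Directions of these lists depended on the scale. With shTMLHE 1, medians below 0 lay above 0 under total counts for the Fanconi pathway (0.21), end joining (0.30), carnitine genes (0.18), beta-oxidation (0.18), acetyl-CoA supply (0.25), histones (0.26) and the interferon response (0.21). With shTMLHE 2 the same held for the Fanconi pathway (0.26), carnitine genes (0.25), beta-oxidation (0.06), the ATF4 response (0.23), the interferon response (0.33), immediate early genes (0.39) and endothelial markers (0.22). With the GC and length trend removed the median changed sign for histones with shTMLHE 1 (0.12), and with shTMLHE 2 for end joining (-0.04), acetyl-CoA supply (-0.60) and immediate early genes (0.42). Total counts also added calls, for cholesterol biosynthesis (adjusted p = 0.00222 and 3.27e-05 for shTMLHE 1 and 2), the unfolded protein response (0.00801 and 0.00666), the ATF4 response with shTMLHE 1 (0.0281), and the epithelial-mesenchymal list (0.000994) and the demethylases and hydroxylases (0.0411) with shTMLHE 2.

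A direct test between the hairpins asked where their effects differed. With shTMLHE 1, FAM83A was higher than with shTMLHE 2 by 3.17 ± 0.13 (log2, edgeR adjusted p = 2.84e-22), the complement component C3 by 2.87 ± 0.29, ZFP92 by 2.92 ± 0.24, SBK1 by 2.88 ± 0.17 and NACAD by 2.87 ± 0.52. It was lower by 3.64 ± 0.11 for THAP12, and ULBP2, a ligand of an NK cell receptor, stood at -3.15 ± 0.19 and TRIQK at -3.38 ± 0.26. XAGE1B was at -3.34, or -6.51 without shTMLHE 1 replicate 3, and its call was lost without shTMLHE 1 replicate 1 or 2 (-2.83 and -2.75) or shTMLHE 2 replicate 1 or 3 (-3.24 and -3.19), and with the replicate block (adjusted p = 0.0705). In all 9277 genes differed (4811 higher and 4466 lower with shTMLHE 1), 2409 of them at least 2-fold. The number was 7343 with the GC and length trend removed.

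The last comparison asked whether genes changed by CCNE1 moved back with the hairpins. The glucose transporter SLC2A3 fell from 28.6 ± 3.75 to 9.69 ± 1.26 CPM with CCNE1 and stood at 27.5 ± 2.28 and 25.7 ± 1.51 with the hairpins (SD, n = 3). DMBT1 rose from 1.04 ± 0.233 to 8.07 ± 2.70 CPM and stood at 1.27 ± 0.557 and 1.09 ± 0.301. HMGA2 fell by 1.57 with CCNE1 and rose by 1.96 and 3.71 with the hairpins. Its call with CCNE1 was lost without control replicate 3 (-1.25) or CCNE1 replicate 2 (-1.16), and with only the compared groups fitted (adjusted p = 0.0537). CBSL, U2AF1L5 and FTX were also taken by the rule, at 3.45, 2.28 and -1.59 with CCNE1, but share reads with copies or overlapping genes. U2AF1L5 was not called with CCNE1 without control replicate 1 or 3 (2.28 and 2.18) or CCNE1 replicate 2 (1.88) or with only the compared groups fitted (adjusted p = 0.0933), nor FTX without control replicate 3 (-1.18) or CCNE1 replicate 2 or 3 (-1.09 and -1.58). CBSL was at -3.25 with shTMLHE 1, or -1.57 without CCNE1 replicate 3, and lost that call without any of the 3 shTMLHE 1 libraries (-3.35 to -3.19) and with only the compared groups fitted (adjusted p = 0.0984). With shTMLHE 2 it was at -2.26 and lost its call without CCNE1 replicate 3 (-0.59) or any of the 3 shTMLHE 2 libraries (-2.58 to -1.94). That call was also lost with the GC and length trend removed (-1.57), under total counts (-1.74), with the replicate block (-1.83) and with only the compared groups fitted (-2.27).

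In all 1133 genes changed with CCNE1 and in the opposite direction with both hairpins, 749 of them higher with CCNE1 (but 18 of the 80 that passed at 2-fold, or 22.5%), and 2658 changed in the same direction in all 3 comparisons. Independent lists would give 1596 and 1592. Simulated unchanged groups gave 0 opposed genes, but almost no genes were called in them, so this cannot show what the shared libraries add. Under total counts 1464 genes were opposed, 28.8% of them higher with CCNE1 against 66.1% with TMM, and under upper quartile scaling the share was 55.9%. With the GC and length trend removed 1470 genes were opposed and 1353 concordant, where independent lists would give 1120 and 1071. Across genes the CCNE1 and hairpin fold changes correlated at -0.0167 for shTMLHE 1 and 0.0874 for shTMLHE 2, with simulated values of -0.490 and -0.502, since the CCNE1 libraries enter both comparisons with opposite signs. The covariances were -0.0113 and 0.0795 against a simulated -0.0546 for each. These signs were not stable. The correlations were 0.193 and 0.310 over the 12259 genes with a mean log2 CPM of at least 1, against simulated values of -0.498 and -0.504. The covariances over those genes were 0.0751 and 0.175, against a simulated -0.0143 for each. With the GC and length trend removed the correlations were 0.027 and 0.047 over those genes, and -0.133 and -0.107 over all genes. Since sharing alone gave negative values, 0 is not the value of no change here. The simulated fold changes hold noise alone, so the simulated correlations overstate what sharing did to the real ones, and only the covariances can be set side by side.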

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

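The edgeR tests and the list tests of each hairpin in this part were fixed beforehand. The list tests between the hairpins, the fits with the GC and length trend removed or total counts, and the choice of these items were chosen after the result was seen. Of the genes named for the hairpin comparisons, those are given where both hairpins were called in opposite directions. Lists are given where the medians had opposite signs. In each case a direct test between the hairpins passed. Among all tested genes 894 were called in opposite directions, so the genes given here are a small part of them. CCNE1 itself differed by 0.58 (log2, shTMLHE 1 minus shTMLHE 2, edgeR adjusted p = 3.13e-18). It was at 0.34 and -0.24 against the CCNE1 group, and the latter was 0.0954 with the GC and length trend removed and 0.288 under total counts, so the opposite directions may depend on that trend and on the scale.

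CDKN1A, an inhibitor of cyclin-dependent kinases, differed by 1.95 (adjusted p = 6.74e-24), higher with shTMLHE 1 and lower with shTMLHE 2. Its value with shTMLHE 2 was -0.102 with the trend removed and no longer passed. THAP12 differed by -3.64 (adjusted p = 1.00e-26) and TRIQK by -3.38 (2.50e-14). For these 2 genes the rise with shTMLHE 2 shrank to 0.205 and 0.0102 with the trend removed, while the fall with shTMLHE 1 remained.

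FAM83A differed by 3.17 (adjusted p = 2.84e-22), ZFP92 by 2.92 (1.56e-13), SBK1 by 2.88 (7.04e-17) and the NK receptor ligand ULBP2 by -3.15 (3.18e-17). With the trend removed FAM83A was at 0.0789 with shTMLHE 1, no longer passing (0.268 as counted), and at -2.80 with shTMLHE 2. The other 3 genes stayed past the threshold in opposite directions. Mitochondrially encoded MT-ND4 differed by 0.93 (9.39e-27), and with the trend removed was at 1.03 and -0.193. Under total counts it rose with both hairpins (1.25 and 0.447), while the other 7 genes beside CCNE1 stayed past the threshold in opposite directions. The cause was not tested for these genes.

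Among lists, mitochondrially encoded mRNAs differed by a median of 0.934, at 0.77 with shTMLHE 1 and -0.13 with shTMLHE 2 (camera adjusted p = 9.91e-18, and 0.112 with an estimated correlation). ATF4 response genes differed by a median of 0.36, at 0.22 and -0.30 (adjusted p = 0.0257, and 0.112 with an estimated correlation). Against the CCNE1 group the ATF4 list was called with neither hairpin (adjusted p = 0.323 and 0.329), and mitochondrially encoded mRNAs were not called with shTMLHE 2 (0.0874). Under total counts the medians shared a sign in both lists, at 1.16 and 0.401 for mitochondrially encoded mRNAs and 0.619 and 0.232 for the ATF4 response, so the opposite signs depended on the scale. The cause was not tested.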

How the results depend on the processing

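Counts of changed genes moved most with the 2-fold threshold, to 941 for CCNE1, 2969 for shTMLHE 1, 5852 for shTMLHE 2, 2248 for both hairpins, 2409 between the hairpins and 80 opposed. Leaving out each library gave 6168 to 6500, 8629 to 9124, 10661 to 11057, 6709 to 7039, 8437 to 8694 and 1026 to 1151 in that order. CCNE1 stayed at 4.89 to 4.95 with CCNE1 overexpression, and TMLHE at -4.29 to -3.87 with shTMLHE 1 and -5.45 to -4.72 with shTMLHE 2. With the replicate block the counts were 6624, 9231, 11123, 7130, 9125 and 1100. Lists past the threshold went from 10, 10 and 6 to 4, 5 and 2 with an estimated correlation, and for shTMLHE 2 to 11 with the GC and length trend removed. With fry, which tests a list against no change and so asks another question, 17, 23 and 23 passed.

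Several small gene values changed sign. With CCNE1 overexpression, TMLHE went from -0.203 to 0.0384 with libraries left out (0.0107 without control replicate 1), ALDH9A1 from -0.0117 to 0.0897, and RAD51C was at -0.114 with the GC and length trend removed. CPT1A was at 0.00734 with DESeq2, 0.0185 with the replicate block, 0.058 with the trend removed and -0.310 to 0.375 with libraries left out. With shTMLHE 1, RAD51C was at 0.372 under total counts and -0.120 to 0.0372 with libraries left out, and CPT2 at 0.0278 under total counts. With shTMLHE 2, CCNE1 was at 0.0954 with the trend removed and 0.288 under total counts, RAD51C at -0.0874 with the trend removed, and CPT2 and SLC25A20 at 0.343 and 0.209 under total counts. None of these genes but CCNE1 and RAD51C with shTMLHE 2 had passed, and the cause was not tested.

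Lists whose test changed direction had not passed, and where this was with fry the question differed too. With CCNE1 overexpression the adjusted p values were 0.164 with fry and 0.836 to 0.981 with libraries left out for acetyl-CoA supply. With the trend removed they were 0.977 for deacetylases, 0.178 for glycolysis and 0.764 for immediate early genes. With shTMLHE 1 they were 0.995 with the trend removed for carnitine genes, 0.884 under total counts for endothelial markers, and for histones 0.228 with fry, 0.395 under total counts and 0.863 to 0.978 with libraries left out. With shTMLHE 2 they were 0.964 under total counts for acetyl-CoA supply, 0.797 with fry for immediate early genes, and 0.584 with fry and 0.69 under total counts for endothelial markers. For histones with shTMLHE 2 they were 0.00128 with fry, 0.955 with RLE, 0.398 under total counts and 0.944 to 0.995 with libraries left out.

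Among other gene values 30 calls were lost and 5 gained with a library left out, 8 were lost and 1 gained with the trend removed, 1 was lost and 1 gained under total counts, and 8 were lost with only the compared groups fitted. With the replicate block 2 were lost, CBSL with shTMLHE 2 (adjusted p = 0.087) and XAGE1B between the hairpins (0.0705). Numbers of the replicates did not pair libraries across groups, since 2 of 12 libraries correlated best with their own number.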

Other observations

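The edgeR fit was fixed beforehand, and all tests of explanations and the genes named in this part were chosen after the result was seen. Metallothionein genes outside the naming rule were looked at because MT1E, MT1M and MT1X rose with both hairpins. MT2A stood at 412 ± 13.1 CPM with CCNE1, 1302 ± 64.7 with shTMLHE 1 and 656 ± 45.2 with shTMLHE 2 (SD, n = 3), and rose by 1.66 and 0.67 on the log2 scale (edgeR adjusted p = 2.68e-25 and 1.71e-15). MT1F rose by 2.54 and 1.35. MT1L was at 0.28 with shTMLHE 1, without passing, and fell by 0.49 with shTMLHE 2. With the GC and length trend removed the values were 2.38 and 2.00 for MT2A, 3.17 and 2.45 for MT1F, and for MT1L 0.63 with shTMLHE 1, which passed, and 0.09 with shTMLHE 2, which did not. The cause was not tested.

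FAM71E1, which overlaps EMC10 on chromosome 19, was named after its values were seen. It shared 20.7% of its exon bases with genes on the other strand, and the strand setting of the counting was not stated, so the source of its reads is uncertain. It had 45, 38 and 25 counts in the control libraries and 0 in all 9 others, while EMC10 had 657, 607 and 499 counts in control and at most 4 elsewhere. With a floor of 3 counts per group, FAM71E1 was at least 43.2-fold lower with CCNE1, 48.3-fold with shTMLHE 1 and 57.9-fold with shTMLHE 2. At an equal total of 14054101 counts, 18816 ± 48.2 genes were detected in control, 18259 ± 181 with CCNE1, 21487 ± 172 with shTMLHE 1 and 22219 ± 235 with shTMLHE 2 (SD, n = 3). The 50 genes with most counts took 23.9 to 24.4% of counts in control and CCNE1 libraries and 15.3 to 18.2% in hairpin libraries. The depth left for other genes was therefore not equal. The cause was not tested.

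Ribosomal protein and oxidative phosphorylation genes were lower with both hairpins, and the GC content and transcript length trend could have caused this. With the trend removed the weakest of the 4 list medians was -0.693. At most 0.03% of 10000 random lists matched on GC content, length and expression were as low as counted, and 0% with the trend removed. These lists were drawn gene by gene and lack the correlation of real members, estimated at 0.23 to 0.24 for ribosomal proteins and 0.0246 to 0.0341 for oxidative phosphorylation. The closeness of the match was not measured either, so the percentages may be too small. With the trend removed, camera with an estimated correlation still called both lists with both hairpins (adjusted p = 0.000104 to 0.0014). This argues against that trend, as modelled, as the whole cause. Matched lists also fell with the trend removed, with shTMLHE 1 and 2 medians of -0.392 and -0.435 for ribosomal proteins. For oxidative phosphorylation they were -0.33 and -0.365. Part of the fall was thus shared by genes of like GC content, length and expression. Normalization factors were tested with library totals, where the highest of the 4 upper quartiles was -0.0666, below 0. Knockdown of TMLHE could be the cause, with 75 of 86 members lower with both hairpins, but no group with another hairpin was labelled, so an effect of any hairpin or of selection stays open.

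BRCA1 was higher with CCNE1 than in control, and the GC content and transcript length trend could have raised it. With the trend removed its log2 fold change was 3.56, well above 0. A gain of the chromosome region would likely raise neighbours too, but the median of the other genes within 1 Mb was -0.228. Another difference between the 2 cell populations stays open, since the labels give a single control and a single CCNE1 population. Among genes with a mean of over 5 CPM in the higher state, 1 gene besides CCNE1, EMC10, was switched at least 15-fold between control and all 3 CCNE1 groups. BRCA1 itself fell just short of that cut, so the count does not show how many genes changed as much as BRCA1.

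Neighbouring genes shifted together between CCNE1 and control. A random arrangement of changed genes was tested with 10000 shuffles. A window counted as beyond the shuffles when its median shift exceeded the largest window shift of 95% of the shuffles. With the trend removed this limit was 0.233, and 6 of 146 windows of 20 Mb lay beyond it. The GC content and transcript length trend did not account for all shifts, as 4 of the 20 windows beyond the shuffles as counted stayed beyond them, in the same direction, with the trend removed. In 4 of the 6 windows beyond the shuffles with the trend removed, at least 75% of genes shifted the same way and both hairpin groups kept at least 50% of the shift against control. These were only partly the same windows as the 4 that were also beyond as counted. Some windows not beyond the shuffles met both conditions too, such as chromosome 10 from 120 to 140 Mb (82.6% of genes). This does not settle whether a copy number carried by the CCNE1 line was the cause, since the comparisons share the control libraries, 67 of the 140 windows not beyond the shuffles kept their shift likewise, and a response to CCNE1 would be kept too. The largest was chromosome 8 from 0 to 20 Mb, with a median of -0.679 over 35 genes, and -0.612 and -0.627 in the hairpin groups against control, though DNA was not measured here.

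Relabelled libraries were refitted for each count of changed genes. For the pairs of groups 10 splits exist, which are too few. The real labels gave 6802, 9338, 11224 and 9277 genes for CCNE1, shTMLHE 1, shTMLHE 2 and the difference between the hairpins, 1 split each being as large, the real split, with a highest other of 0. For lists the real labels gave 10, 10 and 6, with highest others of 4, 5 and 3. For genes changed by both hairpins 2 of 100 regroupings gave as many as the real 7206, the highest other being 7286 with whole groups in exchanged roles, and the highest that mixed groups being 5417. For opposed genes 2 of 100 gave as many as the real 1133, the highest other being 3930, from mixed groups.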
